A study of Mus musculus with 7 samples.

How the data were processed

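Bone marrow cells of mice that had received a bone marrow transplant were profiled on 7 Affymetrix Mouse430_2 arrays. Per the labels, 3 arrays came from recipients of marrow carrying a mock control transgene and 2 from recipients of marrow carrying an ABCG2 transgene. The other 2 came from an unnumbered recipient or recipients of marrow carrying EZH2-Mt, described as MDS-like. MDS is taken here as myelodysplastic syndrome, a disorder of ineffective blood formation. The EZH2-Mt marrow was sorted on GFP (green fluorescent protein) before RNA extraction, with 1 array of GFP-positive and 1 of GFP-negative cells, while mock and ABCG2 marrow was used unsorted. Per the labels' protocols, RNA was taken up in TRIZOL, purified on columns, and 5 micrograms of total RNA were amplified to about 50 micrograms of biotin-labelled cRNA.

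The deposited values are on a log scale, taken as log2, and per the file headers they are normalized signals of probe sets kept by a filter on raw signal from 3 to 120534 and on a Present or Marginal call in 100% of samples. MAS5 is named in the submitters' processing notes, with no version. The scaling between arrays and the probe-level steps were not given in the sources used here. In each of the 16309 probe sets the median over the 7 arrays was 0, so the values had been centred per probe set and carry no absolute level. The base of the logarithm was not stated. The largest range of a probe set over the arrays, 8.70, exceeds the 4.60 that the raw limits allow for base 10 and lies under the 10.6 that they allow for natural logs, so natural logs were not excluded, and every fold given here assumes base 2. The value table of the series held the same values (largest difference 0), and 0 of its columns belonged to other samples. Because of the filter, a gene that was switched off on any array is absent from the values used here, and a large fall is a fall between detected signals.

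The 54 control probe sets of the manufacturer were set apart, which left 16255 probe sets. The platform annotation gave 1 gene symbol for 14229 of them, several for 483 and none for 1543, and no gene was named from a probe set with several. Gene IDs of 14203 probe sets matched the RefSeq gene table of assembly GRCm38.p6, used for names alone, which changed 0 symbols. For gene lists, the value of a gene was the mean over its probe sets, which gave 8378 genes, 3624 of them with more than 1 probe set. No pseudocount was used because the values were already logarithms.

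The comparison of ABCG2 with mock was fitted per probe set with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Values after ± are limma's standard errors unless stated otherwise, and differences are ABCG2 mean minus mock mean in log2. The groups hold 2 and 3 arrays. Each label speaks of a recipient mouse, but mice are not numbered, so p-values measure the spread between these arrays. For the same reason, the 2 sorted fractions cannot be assigned to 1 mouse. For arrays, their number is what limits the precision. The sorted EZH2-Mt fractions hold 1 array each, so their difference has no replicate check and no p-value, and probe sets with a difference of 2-fold or more were counted beside the same counts for pairs of arrays within a group.

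Before the data were examined, 30 gene lists, the tests, the arrays in each fit, the alternatives and a rule for named genes were fixed. The lists cover erythroid cells, neutrophil primary granules and promyelocytes, maturing and mature neutrophils, monocytes and macrophages, B lineage, plasma cells, T and NK cells, stem and progenitor cells, megakaryocytes and platelets, basophils with mast cells and eosinophils, dendritic cells with MHC class II, stroma with bone and vessels, cell cycle, p53 targets, interferon response, NF-kB with inflammatory cytokines, immediate early genes, heat shock and protein folding stress, Polycomb complexes, Hox genes and partners, regulators repressed by Polycomb, ABC transporters, heme synthesis and iron, oxidative stress defence, ribosomal proteins, glycolysis and hypoxia, apoptosis regulators, genes mutated in human MDS, TGF-beta signalling, and sex-linked transcripts as a sample check. Some genes stand in several lists, among them 4 of the erythroid, 2 of the monocyte, 3 of the stem and progenitor and 8 of the heme and iron genes measured. At least 1 member was measured in 29 lists, and 0 members of the sex-linked list were. The 25 lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data. With an estimated correlation, camera takes its p from the few residual degrees of freedom of these arrays, so hardly any list could pass. Camera compares a list with the other genes. Fry was run as well, and it tests whether the genes of a list moved on balance in 1 direction, so its values answer another question. For the sorted fractions, the median of a list was ranked among medians of 10000 random lists of the same size. These were not matched on level, since the values carry none, and they take no account of genes that vary together. The same count was therefore made for each pair of mock arrays, after the data were seen.

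The rule for named genes took Abcg2 and Ezh2 always, then the 12 largest rises and 12 largest falls that passed the threshold with every ABCG2 array beyond every mock array, the 12 highest and 12 lowest differences between the sorted fractions, and from each list up to 4 members that passed by size, or 2 by size where fewer passed, with up to 3 by size between the fractions. Clone names were skipped. The rule also asked that the brighter array of the sorted fractions lie above the median signal, which could not be applied to centred values. Members of the Gimap family beyond those taken by the rule were chosen after their values were seen. So were list members named because they did not pass or moved against most of their list.

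On simulated data with the same numbers of arrays and 16255 probe sets, the limma fit recovered 33% of 100 changes of 1 log2 and 89% of 100 changes of 3 log2, with 2 false calls, and the list test found the 1 shifted list of 25 with 0 false lists. Simulated probe sets varied independently and few were changed, whereas 56.8% were called in the data. Estimated correlations within lists reached 0.91 in the data, so the simulation cannot show how often camera calls false lists there.

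Some planned steps met values of another kind than assumed. The plan had a variance trend with signal level, and since centred values carry no level the fit used none and the trend became an alternative. The brightest probe set of a gene could not be chosen, so the mean was used. A filter on detection had already been applied, so the alternatives without a filter and with a stricter one changed nothing and say nothing about stability, and other pseudocounts were not run. The remaining alternatives were quantile normalization, median centring of arrays, 1 value per gene, the replicate number as a block, all 7 arrays in the fit, array weights, and each replicate left out in turn. The variance trend, the first probe set per gene and a 2-fold minimum beside the threshold were added after the data were seen. Quantile normalization gives every array the same spread by construction.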

Results

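Expression was measured in whole bone marrow of mock (3 arrays) and ABCG2 recipients (2 arrays). It was also measured in GFP-positive and GFP-negative EZH2-Mt marrow (1 array each). The series compares marrow that expresses genes altered in MDS with control marrow. ABCG2 is a drug efflux pump of stem and progenitor cells, and EZH2 is the histone methyltransferase of Polycomb repressive complex 2. After centring, the SD over 16255 probe sets was 0.42, 0.33 and 0.35 log2 on the mock arrays, 0.41 on the GFP-negative array, 0.54 on the GFP-positive array, and 1.06 and 1.13 on the ABCG2 arrays. Across probe sets the ABCG2 arrays correlated with each other at r = 0.90, against 0.43 to 0.63 between mock arrays. Arrays that lie far from the centring median share that distance, so this r does not measure agreement of replicates. The ABCG2 arrays differed 2-fold or more in 891 probe sets, against 109 to 410 between mock arrays. The titles of the ABCG2 arrays carry a tag that the other titles lack and whose meaning the labels do not give. If it marks a batch, that batch and the ABCG2 group cannot be told apart.

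In whole marrow of ABCG2 recipients, 19 of 20 mature neutrophil genes, 6 of 6 primary granule genes and 11 of 14 monocyte genes fell against mock marrow, and 6 of 10 B-lineage genes rose (n = 2 against 3 arrays). Of all 8378 genes in the same fit, 2983 rose and 2196 fell. List counts near those shares are not particular to a list. The neutrophil and monocyte lists passed limma's camera but not with an estimated correlation (adjusted p from 0.577 to 0.818), and the B lineage did not pass it (adjusted p = 0.0943). With so few arrays, hardly any list could pass at an estimated correlation. The largest fall was in Thbs1, which encodes the platelet and monocyte protein thrombospondin 1, by 8.19 ± 0.23 log2 (292-fold). Mpo, the peroxidase of neutrophil primary granules, fell by 6.68 ± 0.33, and the neutrophil collagenase gene Mmp8 fell by 6.71 ± 0.51. Among the rises, Socs2, a feedback inhibitor of cytokine signalling, was higher by 7.20 ± 0.38 (147-fold), and Il7r, the interleukin-7 receptor chain needed for lymphocyte development, by 5.93 ± 0.34. Ly6d, a marker of progenitors committed to the B lineage, rose by 5.86 ± 0.29.

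The other large falls were in Cd300lb (-6.86 ± 0.40), Clec4a2 (-6.54 ± 0.41) and Anxa3 (-6.26 ± 0.32), of myeloid cells. Ms4a3, a marker of granulocyte-monocyte progenitors, fell by 6.26 ± 0.33, and F13a1, which encodes coagulation factor XIII chain A, fell by 6.37 ± 0.14. Falls of similar size were those of the transcription factor gene Ets2 (-6.26 ± 0.45), the fibronectin gene Fn1 (-6.23 ± 0.17), and Pxylp1 (-6.27 ± 0.29) and Csgalnact2 (-6.25 ± 0.23), both of proteoglycan synthesis. The other large rises were in Apold1 (6.39 ± 0.36), Grhpr (5.34 ± 0.18), which encodes glyoxylate reductase, Snn (5.09 ± 0.96), the NK cell receptor gene Klrd1 (5.01 ± 0.63) and Nlrc3 (5.01 ± 0.43). Spib, an Ets factor of B cells and plasmacytoid dendritic cells, rose by 4.84 ± 0.45. These were followed by the calponin gene Cnn3 (4.76 ± 0.19, with 3.60 to 4.76 over its 6 probe sets), and Gimap4 (4.75 ± 1.26) and Gimap6 (4.67 ± 0.59), which encode GTPases of lymphocytes. All 24 of these genes passed limma's test, which the rule for naming them required, with adjusted p from 1.76e-05 to 0.0178. With quantile normalization Snn (adjusted p = 0.0687) and Gimap4 (adjusted p = 0.0549) no longer passed, and Gimap4 did not pass without ABCG2 replicate 2 (adjusted p = 0.0596). The Il7r difference came with low values in mock marrow, from -4.84 to -3.74, while the sorted EZH2-Mt fractions lay at 0 and 1.43, near the ABCG2 arrays at 1.35 and 1.95. Mock values were low for Klrd1 too, from -3.48 to -1.13, with GFP-negative at 2.58, GFP-positive at 0, and ABCG2 at 2.54 and 2.98. For Nlrc3 they ran from -3.27 to -1.82, with GFP-negative at 0.72, GFP-positive at 0, and ABCG2 at 2.64 and 2.71.

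**Figure D1:**
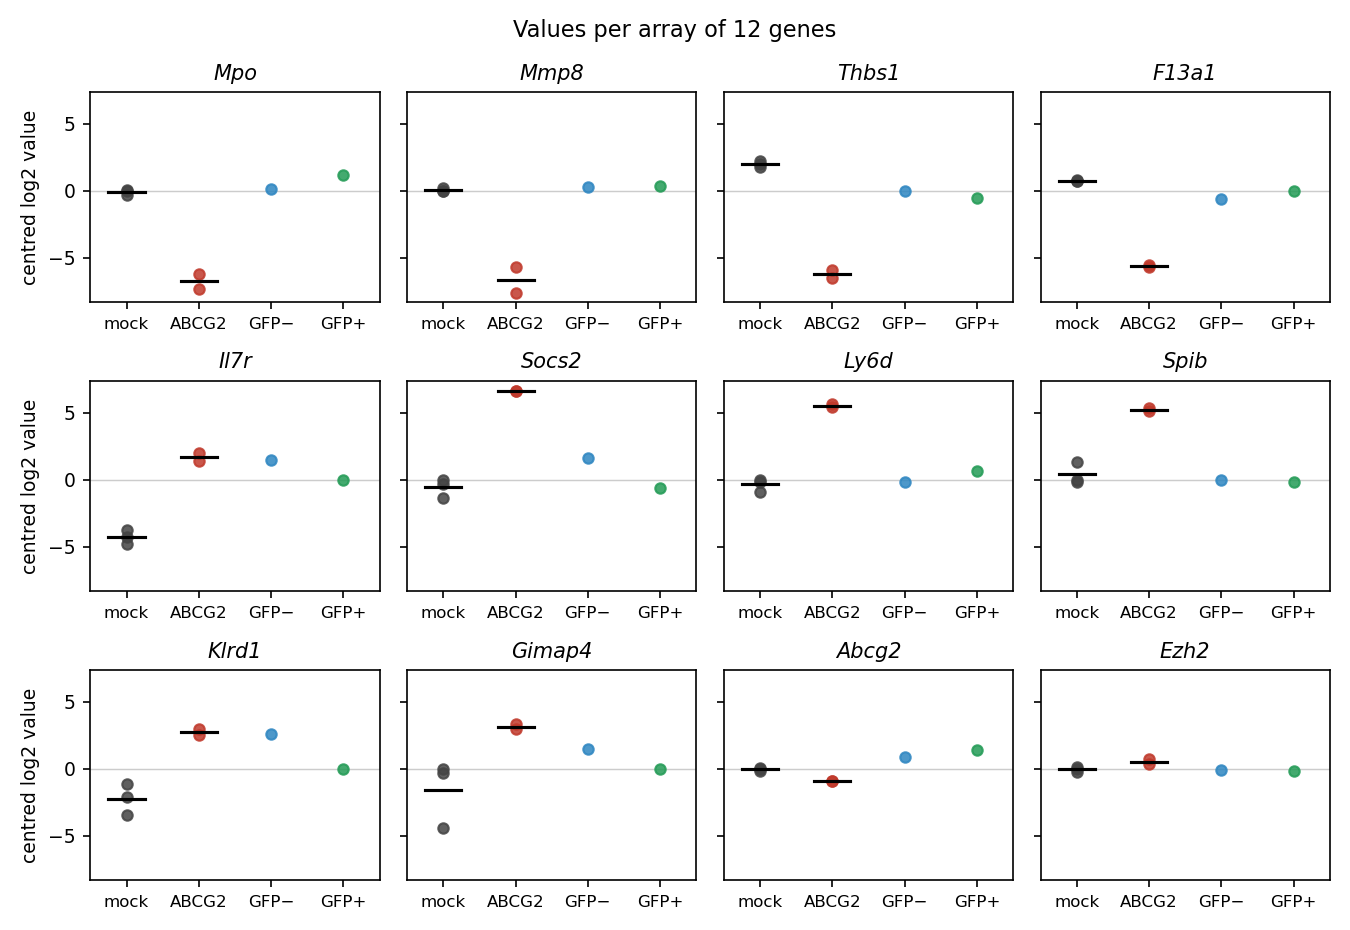
Centred log2 values (vertical axis) of 12 genes on each of the 7 arrays, by group on the horizontal axis, with points for arrays and black bars for the means of mock (n = 3) and ABCG2 (n = 2). Mpo, Mmp8, Thbs1 and F13a1 lie below -5 on both ABCG2 arrays, whereas Il7r differs because the mock arrays lie low, from -4.84 to -3.74. Klrd1 also lies low on the mock arrays, from -3.48 to -1.13.

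The genes named in the transgenes differed by under 1 log2 between ABCG2 and mock marrow. Centred Abcg2 values were lowest on the ABCG2 arrays (-0.92 and -0.91) and lay from -0.17 to 0.02 on mock arrays. They were highest on the EZH2-Mt arrays (0.84 GFP-negative, 1.35 GFP-positive). Abcg2 fell by 0.86 ± 0.14 on the arrays labelled ABCG2 (limma, adjusted p = 0.00276), and with quantile normalization the difference was -0.49 with an adjusted p of 0.151. The species of the transgene and whether the probe set covers it were not given in the sources used here, so these Abcg2 values do not check the labels. Directions below hold for the arrays labelled ABCG2. Relative to mock, Ezh2 was higher by 0.54 ± 0.18 (adjusted p = 0.0405). That limma call was lost with quantile normalization (difference 0.23, adjusted p = 0.525), array weights (0.47, adjusted p = 0.0680) and the replicate block (0.56, adjusted p = 0.0551). It was also lost without mock replicate 1, 2 or 3 (differences 0.45, 0.63 and 0.56, adjusted p from 0.0559 to 0.0973). Without ABCG2 replicate 2 the difference was 0.38.

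Neutrophil transcripts fell almost as a body. Of 6 measured genes of primary granules and promyelocytes, all 6 fell (6 adjusted over the list alone), with a median of -5.92, as in Mpo, Ms4a3, the cathepsin G gene Ctsg (-6.13 ± 0.27) and the proteinase 3 gene Prtn3 (-5.71 ± 0.21). Camera, with limma, gave an adjusted p of 0.000545, and the adjusted p = 0.596 with an estimated correlation. Of 20 genes of maturing and mature neutrophils, 19 fell (19 adjusted over the list alone) and 0 rose, with a median of -4.99 and a camera adjusted p of 9.35e-08, against adjusted p = 0.818 with an estimated correlation. Examples are Mmp8, the C-type lectin gene Clec4d (-6.20 ± 0.45), G0s2 (-6.17 ± 0.63) and Cd177 (-6.02 ± 0.43). The member that did not pass was Stfa3, at -0.40.

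Monocyte and macrophage genes fell in 11 of 14 cases (12 adjusted over the list alone), with 0 higher and a median of -3.31. F13a1, the endotoxin coreceptor gene Cd14 (-6.05 ± 0.34), the iron exporter gene Slc40a1 (-4.59 ± 0.20) and the macrophage perforin gene Mpeg1 (-4.36 ± 0.18) were the largest. The camera adjusted p was 2.14e-05, and the adjusted p = 0.577 with an estimated correlation. Megakaryocyte and platelet genes fell in 6 of 7 cases (6 adjusted over the list alone), among them Thbs1, the P-selectin gene Selp (-2.88 ± 0.16), platelet factor 4 (Pf4, -2.42 ± 0.56) and Fli1 (-1.29 ± 0.18), with a median of -1.29. The camera adjusted p was 0.00881, and the adjusted p = 0.577 with an estimated correlation. Of 5 basophil, mast cell and eosinophil genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -4.95. Mcpt8 (-6.03 ± 0.35), eosinophil peroxidase (Epx, -5.55 ± 1.02), Prg2 (-4.95 ± 0.71) and Il6 (-4.91 ± 0.64) fell, and Cpa3 (0.81 ± 0.18) rose. That list missed the threshold (camera with limma, adjusted p = 0.0943) and passed it without mock replicate 1 (0.0378) or ABCG2 replicate 1 (0.0495) (fry 0.0314). Of 7 dendritic cell and MHC class II genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with Tcf4 at 2.54 ± 0.18, H2-DMa at -1.55 ± 0.21 and Itgax at -0.99 ± 0.31. The list median of -0.87 did not pass (adjusted p = 0.345), except without mock replicate 1 (median -1.28, adjusted p = 0.0346).

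**Figure D2:**
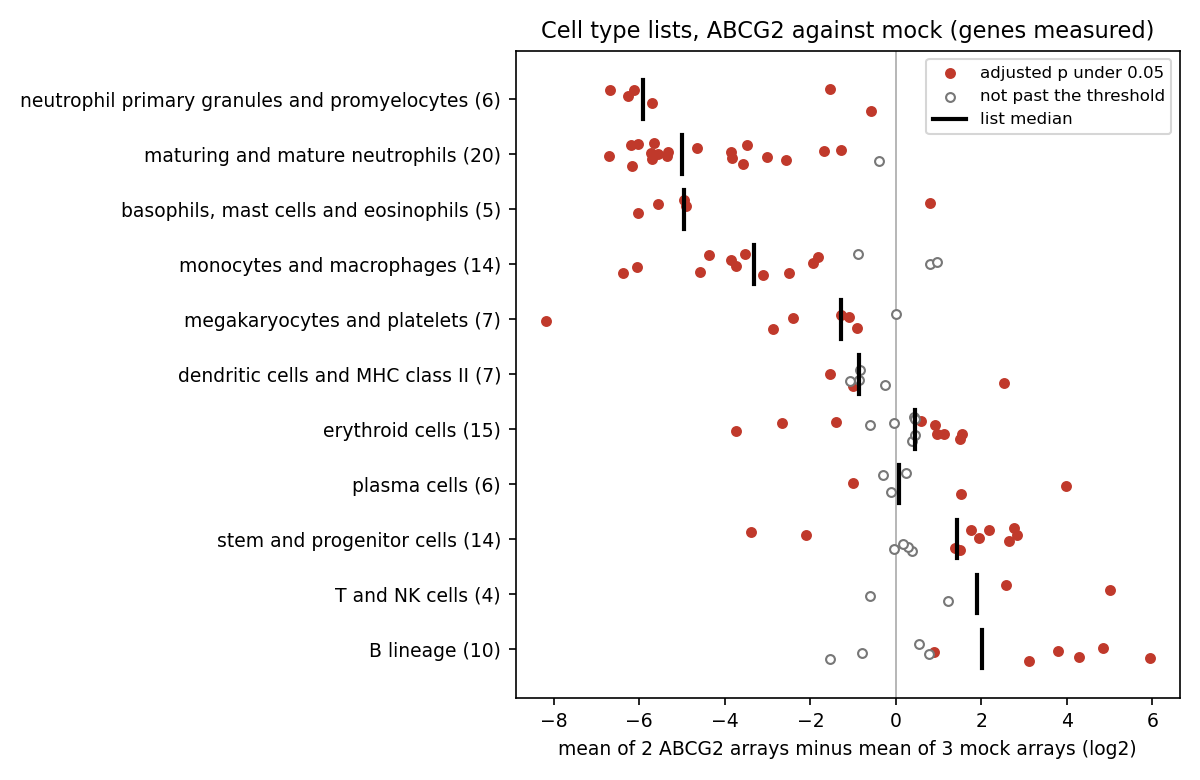
Difference between the mean of 2 ABCG2 and 3 mock arrays in log2 (horizontal axis) for each measured gene of 11 cell type lists (vertical axis, genes measured in brackets), with filled points for limma adjusted p under 0.05, open points for the others, and black bars for list medians. Medians run from -5.92 for neutrophil primary granules to 2.01 for the B lineage.

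B-lineage genes rose in 6 of 10 cases (6 adjusted over the list alone), with 0 lower past the threshold and a median of 2.01. The rises included Il7r, Spib, the coactivator gene Pou2af1 (4.28 ± 0.28) and the B cell receptor gene Cd79b (3.79 ± 0.25). Members that did not pass were Blnk (0.77), Ms4a1 (0.54), Bank1 (-0.78) and Ighm (-1.54). As a list they did not pass camera (limma, adjusted p = 0.0943), but did with quantile normalization (0.0295) and without mock replicate 2 (0.0476). Fry, which asks whether the genes of a list moved on balance in 1 direction and not whether they moved more than other genes, gave 0.00979. Of 4 measured T and NK cell genes, too few to test, 2 rose (2 adjusted over the list alone), Klrd1 and the costimulatory receptor gene Cd28 (2.58 ± 0.70). Mock replicate 1 differed from the other mock arrays in this list by a median of -1.93, beside a list median of 1.90 for ABCG2 minus mock. In Cd28 it lay at -2.48, against -0.23 and -0.73 on the other mock arrays. Plasma cell genes split, with 2 of 6 higher and 1 lower (2 and 1 adjusted over the list alone). Mzb1 (3.99 ± 0.30) and the immunoglobulin J chain gene Jchain (1.52 ± 0.38) rose and Edem1 (-1.003 ± 0.18) fell (list median 0.06, with -0.10 to 0.33 when 1 array was left out, adjusted p = 0.941).

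Stem and progenitor genes rose in 8 of 14 cases and fell in 2 (9 and 2 adjusted over the list alone), with a median of 1.44 and a camera adjusted p of 0.110 (fry 0.00823). The receptor tyrosine kinase gene Flt3 (2.84 ± 0.32), Egfl7 (2.77 ± 0.17) and Sox4 (2.65 ± 0.26) rose, while Angpt1, a niche factor, fell by 3.39 ± 0.14. Lmo2 fell as well (-2.11 ± 0.14). Erythroid genes went both ways, 6 of 15 higher and 3 lower (6 and 3 adjusted over the list alone). The erythroid transcription factor gene Nfe2 (-3.73 ± 0.18) and carbonic anhydrase 1 (Car1, -2.65 ± 0.61) fell, and the transferrin receptor gene Tfrc (1.54 ± 0.13) and Cpox (1.497 ± 0.16), of heme synthesis, rose. The erythroid median was 0.44 and the mean -0.01 (camera adjusted p = 0.635). The median was 0.67 without mock replicate 3 and -0.01 without mock replicate 1, which was itself lower than the other mock arrays in erythroid genes by a median of -0.65. The 1 measured gene of stroma, bone and vessels, the osteoclast phosphatase gene Acp5, rose by 2.20 ± 0.28.

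Among process lists, only cell cycle passed camera, downward: 13 of 37 genes fell and 4 rose (13 and 3 adjusted over the list alone), with a median of -0.38 and a limma camera adjusted p of 0.0331, against adjusted p = 0.871 with an estimated correlation. Cyclin E2 (Ccne2, -1.30 ± 0.19), the kinesin gene Kif11 (-1.16 ± 0.17), Prc1 (-1.15 ± 0.22) and Mki67 (-1.11 ± 0.20) fell. The 4 that rose were Mcm2 (0.99 ± 0.19), Mcm4 (0.66 ± 0.14), Mcm6 (0.63 ± 0.13) and Mcm7 (0.41 ± 0.14). The call was lost with quantile normalization (0.106), without mock replicate 3 (0.0762) and without ABCG2 replicate 1 (median -0.09, adjusted p = 0.322), while the median was -0.58 without ABCG2 replicate 2. Fry, which does not compare a list with other genes, gave 0.220. NF-kB and inflammatory cytokine genes fell in 9 of 18 cases and rose in 4 (9 and 4 adjusted over the list alone), among the falls Il6, Il1b (-4.90 ± 0.31), Cxcl2 (-4.74 ± 0.78) and Tnfaip2 (-4.65 ± 0.45). The list median of -0.95 did not pass (adjusted p = 0.0673), and passed without mock replicate 1 (0.0123), without ABCG2 replicate 1 (0.0412), and with array weights (0.0307) (fry 0.0314). Interferon response genes fell in 8 of 24 cases and rose in 3 (7 and 3 adjusted over the list alone), with the viral RNA sensor gene Ifih1 (-3.21 ± 0.16), Trim30a (-1.69 ± 0.23), Mx1 (-1.54 ± 0.36) and Cmpk2 (-1.38 ± 0.20) lower. The interferon median of -0.32 had an adjusted p of 0.143. That list passed without ABCG2 replicate 2 (median -0.62, adjusted p = 0.00770) and with quantile normalization (0.0445), while its median was -0.06 without ABCG2 replicate 1.

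Redox and iron genes moved in both directions. In oxidative stress defence 9 of 20 fell and 8 rose (9 and 8 adjusted over the list alone). The microsomal glutathione transferase gene Mgst1 (-6.10 ± 0.34), glutaredoxin (Glrx, -4.77 ± 0.19) and glutathione reductase (Gsr, -3.82 ± 0.16) fell and peroxiredoxin 2 (Prdx2, 2.66 ± 0.12) rose. The list median was -0.01, with -0.10 to 0.07 when 1 array was left out (camera adjusted p = 0.398, fry 0.00823). In heme synthesis and iron 10 of 26 fell and 8 rose (10 and 8 adjusted over the list alone). Slc40a1 and Alas1 (-2.22 ± 0.14), the first enzyme of heme synthesis outside red cells, fell, and Abcb6 (1.57 ± 0.22) and Tfrc rose (median -0.18, adjusted p = 0.586, fry 0.0499), with medians of -0.03 without ABCG2 replicate 1 and -0.28 without ABCG2 replicate 2. Glycolysis and hypoxia genes fell in 10 of 21 cases and rose in 4 (10 and 4 adjusted over the list alone). The glucose transporter gene Slc2a3 (-2.52 ± 0.14) and Ero1a (-2.03 ± 0.20) fell, and Pdk1 (1.97 ± 0.13) and Egln3 (1.97 ± 0.18) rose (median -0.44, adjusted p = 0.0943, fry 0.00414). ABC transporter genes rose in 7 of 17 cases and fell in 5 (7 and 5 adjusted over the list alone). The cholesterol exporter gene Abca1 (1.89 ± 0.14) rose, and Abcc5 (-1.64 ± 0.16) and Abca7 (-1.46 ± 0.14) fell (median 0.33, or 0.08 without mock replicate 1, adjusted p = 0.941).

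Of 23 genes of Polycomb complexes 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Bmi1 (2.18 ± 0.17), Cbx6 (1.65 ± 0.14) and Mtf2 (0.95 ± 0.13) higher and Phf1 (-1.27 ± 0.17) lower. Their median of 0.43 did not pass camera (adjusted p = 0.156, and adjusted p = 0.784 with an estimated correlation; fry 0.00823). The only measured gene of the Hox list was the Hox partner Pbx3, which fell by 3.90 ± 0.28, and the only measured regulator repressed by Polycomb was Lin28a, which fell by 3.90 ± 0.22. Of 24 genes mutated in human MDS, 6 rose and 4 fell (6 and 4 adjusted over the list alone). Idh1 (-3.26 ± 0.15) and Stag2 (-1.01 ± 0.13) fell, and Dnmt3a (1.68 ± 0.18) and Ptpn11 (0.88 ± 0.13) rose (median 0.19, adjusted p = 0.827). Ribosomal protein genes rose in 10 of 36 cases (9 adjusted over the list alone) with 0 lower, for example Rpl14 (1.93 ± 0.18), Rpl12 (1.79 ± 0.30), Rps3 (1.16 ± 0.13) and Rps6 (1.08 ± 0.16), with a median of 0.15, or 0.06 without mock replicate 1 (adjusted p = 0.174). That share of rises was below the share over all genes, 2983 of 8378.

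The remaining lists had members on both sides. Apoptosis regulators rose in 6 of 20 cases and fell in 6 (6 and 6 adjusted over the list alone). The survival gene Bcl2 (3.14 ± 0.25), Bmf (2.22 ± 0.25), Diablo (1.99 ± 0.13) and Casp6 (1.67 ± 0.23) rose. The median of that list was -0.20 and its mean 0.24, while camera pointed down (adjusted p = 0.635). For p53 targets, 4 of 14 rose and 3 fell (4 and 3 adjusted over the list alone). Gadd45a (-3.21 ± 0.24) fell, and Ddit4 (3.08 ± 0.40), Sesn1 (2.26 ± 0.20) and Aen (1.55 ± 0.22) rose (median 0.05, with -0.01 to 0.19 when 1 array was left out, adjusted p = 0.941). Of 19 immediate early genes 4 rose and 3 fell (2 and 2 adjusted over the list alone). Egr2 (3.17 ± 0.26) and Myc (2.42 ± 0.65) rose, and Klf4 (-2.21 ± 0.29) and Klf6 (-1.75 ± 0.24) fell (median 0.53, or 0.18 without mock replicate 1, adjusted p = 0.827). Of 19 genes of heat shock and protein folding stress 4 rose and 6 fell (4 and 6 adjusted over the list alone). The asparagine synthetase gene Asns (-3.22 ± 0.13) and Dnajb9 (-1.003 ± 0.22) fell, and the chaperone genes Hspe1 (1.60 ± 0.19) and Hsph1 (1.45 ± 0.32) rose (median -0.34, or -0.20 without ABCG2 replicate 2, adjusted p = 0.262). Of 14 TGF-beta signalling genes 4 rose and 3 fell (2 and 3 adjusted over the list alone). Thbs1 and Tgfbi (-5.04 ± 0.17) fell, and Smad7 (1.997 ± 0.70) and Smad3 (1.76 ± 0.17) rose (median -0.31, or -0.08 without ABCG2 replicate 2, adjusted p = 0.386, fry 0.0250). For p53 targets and ABC transporters, camera pointed down although the medians lay above 0.

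In all, 9234 of 16255 probe sets (56.8%) differed between ABCG2 and mock marrow at a limma adjusted p under 0.05, 5122 higher and 4112 lower, and 10088 had an unadjusted p under 0.05. They covered 3323 genes with a higher and 2499 with a lower probe set, 126 of them in both. Falls reached further than rises, with 180 probe sets lower and 25 higher by 16-fold or more, while 2434 were lower and 2609 higher by 2-fold or more. Every ABCG2 array lay beyond every mock array in 11894 probe sets (73.2%, against 20% by chance), and the median difference of all probe sets was 0.11. With quantile normalization the counts were 1988 higher and 2381 lower. Of the 25 lists 5 passed camera, all of them lower, and 0 passed with an estimated correlation. The megakaryocyte and platelet list lost its call although its estimated correlation, -0.06, lay below the preset 0.01. The loss of calls in that setting thus cannot show whether correlation among genes undoes them. By fry, which compares no list with other genes, 13 passed.

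Controls added during labelling and hybridization also differed between these groups. The hybridization control bioB, added at the lowest amount of the 4 such controls, was lower on both ABCG2 arrays than on mock arrays. Its median on each array, relative to the mock mean, was -2.997 and -3.16 log2. The median over probe sets of the difference between the group means was -3.18 for bioB, -0.59 for bioC, -0.11 for bioD and -0.21 for cre. The poly-A controls lay at -0.96 and -1.51 relative to the mock mean. The difference of the 3' from the 5' probe set of beta-actin, a sign of RNA integrity, was 0.42 larger on the ABCG2 arrays than on mock arrays, and that of Gapdh differed by -0.08.

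**Figure D3:**
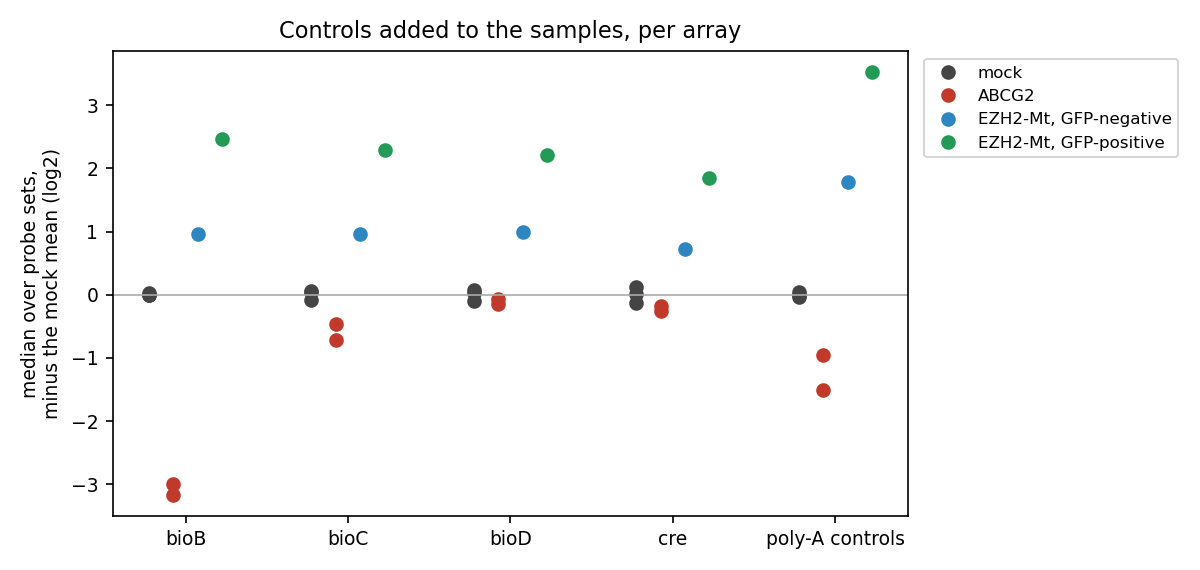
Median over probe sets of each added control, relative to the mock mean in log2 (vertical axis), on every array, for the hybridization controls bioB, bioC, bioD and cre and the poly-A controls (horizontal axis). Both ABCG2 arrays lie near -3 for bioB, and the GFP-positive array lies above all others in each control.

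Between the sorted EZH2-Mt fractions, 15 of 15 erythroid, 5 of 6 plasma cell and 5 of 6 neutrophil granule genes were higher in the GFP-positive than in the GFP-negative cells (1 array each). All 4 T and NK cell genes were lower, by a median smaller than the 2.30 between a pair of mock arrays. The immunoglobulin heavy chain gene Igha was higher by 2.80 log2 (6.99-fold), and Jchain, which joins immunoglobulin A and M, by 2.35. The erythroid master regulator Klf1 was higher by 1.64, as much as its range over the mock arrays. In the other direction, the NK receptor genes Klrc1 and Klrd1 were at -3.03 and -2.58, and the long noncoding RNA Malat1 at -3.24.

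The rest of the 12 highest differences belonged to Pttg1ip (2.40), an immunoglobulin kappa variable gene (2.36), Vill (2.19), Kctd14 (2.11), the protease gene Ctse (2.05), the calcium channel gene Cacna1d (2.05), the DNA repair gene Xrcc3 (2.04), Nme1 (2.004), Kif3b (1.98) and Dtl (1.955). The rest of the 12 lowest belonged to Ms4a4b (-2.39), Itm2a (-2.36), Crebzf (-2.33), Serpinb2 (-2.28), Tmem64 (-2.26), Socs2 (-2.24), Il6 (-2.17), Ctla2b (-2.10) and the ribosomal protein gene Rps10 (-1.98). Of the 24 genes 13 had more than 1 probe set, and in 10 of these the probe sets lay over 1 log2 apart, as in Malat1 (-3.24 to -0.13), Rps10 (-1.98 to 0.53) and Pttg1ip (-0.46 to 2.40). For Igha, Ctse and Serpinb2 the mock arrays themselves spanned 2.998, 3.27 and 4.10. Ezh2 differed by -0.02 and Abcg2 by 0.52 between the fractions.

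Erythroid genes were higher in the GFP-positive cells in 15 of 15 cases, with a median of 1.17, led by Klf1, Ermap (1.55) and the tetraspanin gene Tspan33 (1.43). Over the mock arrays these 3 genes spanned 1.64, 2.47 and 1.06, and 7 of the 15 erythroid genes differed by more than such a range. Plasma cell genes had a median of 1.20 over 6 genes, with Igha (2.59 as the mean of its probe sets), Jchain and the syndecan 1 gene Sdc1 (1.62) highest, and 5 of 6 above 0. Neutrophil primary granule genes had a median of 0.81, as in Mpo (1.04), Ms4a3 (0.91) and Prtn3 (0.81), while mature neutrophil genes had a median of 0.11 (-0.01 with quantile normalization), inside the range of random lists, with Ngp (1.10), S100a9 (1.03) and Camp (0.89) the largest. Of the 20 mature neutrophil genes 11 lay above 0 and 9 below, the lowest being Clec4e (-0.76, against a mock range of 0.42). For the B lineage the median was 0.66, with 6 of 10 genes above 0 and 4 below. Blnk (1.69) and Ms4a1 (1.24) were higher and Il7r (-1.43) was lower, against mock ranges of 1.89, 1.62 and 1.11, and 3 of the 10 genes differed by more than theirs. Heme synthesis and iron genes (median 0.37) had Slc25a37 (1.17), Tfrc (1.06) and Alad (1.05) highest. Smaller medians above the random range were those of monocytes and macrophages (0.30, with the mannose receptor gene Mrc1 at 1.52), ribosomal proteins (0.30), cell cycle (0.26, with Mki67 at 0.84) and ABC transporters (0.24, with Abcb4 at 0.98).

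The 4 measured T and NK cell genes were all lower in the GFP-positive cells, with a median of -1.496 (Klrd1 -2.58, the chemokine gene Ccl5 -1.63, Cd3d -1.36), against a largest median difference of 2.30 between mock arrays. Medians below the random range were those of basophils, mast cells and eosinophils (-0.68, with Il6 at -2.17 and Cpa3 at -1.04), p53 targets (-0.47, with Ddit4 at -1.49), megakaryocytes and platelets (-0.43, with Fli1 at -0.59), NF-kB and inflammatory cytokines (-0.35, with Il6 and the chemokine gene Ccl4 at -1.59) and immediate early genes (-0.34, with Egr2 at -1.505 and Rgs1 at -1.30). Of these 5 lists, only that of p53 targets differed by more than the largest median difference between mock arrays (0.36), which was 1.62 for basophils, mast cells and eosinophils, 0.45 for megakaryocytes and platelets, 0.70 for NF-kB and inflammatory cytokines and 1.02 for immediate early genes. Among the higher lists, ABC transporters also lay within it (0.27). Altogether 14 of 25 list medians lay outside the central 95% of 10000 random lists, 9 above and 5 below. Pairs of mock arrays, each set against random lists of its own differences, had 5, 12 and 16 of 25 outside, so replicate arrays left that range too.

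Inside that range lay the medians of dendritic cells and MHC class II (0.32, with H2-Aa at 1.26), oxidative stress defence (0.14, with Prdx2 at 1.09), heat shock and protein folding stress (0.12, with the chaperone gene Hyou1 at 1.90), Polycomb complexes (0.01, with Bmi1 at -0.88), and genes mutated in human MDS (-0.02, with Nf1 at 0.76). So did those of stem and progenitor cells (-0.03, with Angpt1 at -1.33), interferon response (-0.08, with Rsad2 at 1.06 and Rtp4 at -1.03), glycolysis and hypoxia (-0.09, or 0.01 with quantile normalization, with Pfkl at 0.76), apoptosis regulators (-0.16, with Bcl2l1 at 1.08) and TGF-beta signalling (-0.17, with Smad7 at -0.87). The single measured genes of the stroma, Hox and Polycomb-repressed lists were Acp5 (-0.62), Pbx3 (-0.28) and Lin28a (-0.61).

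**Figure D4:**
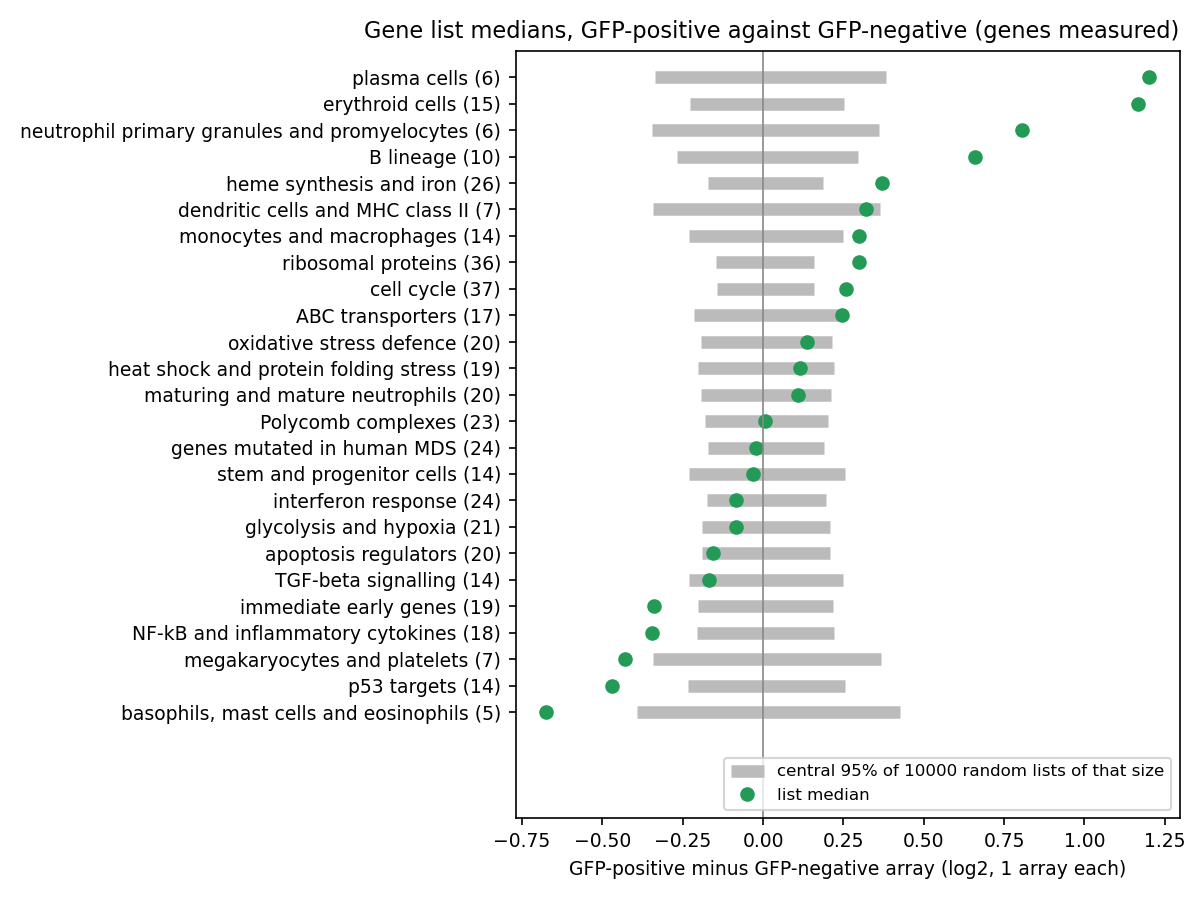
Median difference between the GFP-positive and GFP-negative array in log2 (horizontal axis, 1 array each) for 25 gene lists (vertical axis, genes measured in brackets), with grey bars for the central 95% of 10000 random lists of the same size. Plasma cell and erythroid medians lie at 1.20 and 1.17, and the basophil, mast cell and eosinophil median at -0.68.

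The 2 fractions differed 2-fold or more in 834 probe sets (5.13%), 502 higher and 332 lower in the GFP-positive cells (293 and 261 genes), and 4-fold or more in 21 and 15. Pairs of mock arrays differed 2-fold or more in 109 to 410 probe sets and the ABCG2 pair in 891. With quantile normalization the counts were 804 and 762. Added controls differed too, with hybridization controls higher on the GFP-positive array by a median of 1.28 over probe sets and poly-A controls by a median of 1.63, and the difference of the 3' from the 5' beta-actin probe set was 0.17 larger and that of Gapdh 0.26 larger.

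Set side by side, the ABCG2 and GFP differences of 8378 genes were nearly unrelated (Pearson r = 0.06, Spearman rho = 0.10). This correlation is across genes, which are not independent replicates, and the 2 differences share no array.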

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

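The tests of explanations given here were chosen only after the results they measure were seen. Controls added to the samples, which no comparison of groups uses, lay above every mock array on both sorted EZH2-Mt arrays. Relative to the mock mean, the poly-A controls added to the RNA lay at 1.78 log2 on the GFP-negative and 3.53 on the GFP-positive array, and the hybridization controls at 0.92 and 2.26.

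On the arrays labelled ABCG2, neutrophil, monocyte and megakaryocyte transcripts were lower than in mock marrow. A lower share of neutrophils alone would shift the genes of other cells alike. The B-lineage median exceeded the monocyte median by 5.33. The middle ranges of their differences, -4.23 to -1.86 for monocytes and 0.60 to 4.16 for the B lineage, did not overlap. The falls thus reached beyond the neutrophil lists. These values had already been seen when the pattern was named, so their gap restates it and is no separate test. A change in the cell types that rose stays open. Array handling that differed between the groups cannot be told apart from the group, since bioB differed by -3.18 with every ABCG2 array below every mock array. Of the hybridization controls, bioB, added at the lowest amount, fell most, against -0.59 for bioC, -0.11 for bioD and -0.21 for cre. Whether dim signals of genes were lost likewise was not tested, because the gene values carry no level. A wrong label cannot be told apart from the group either, with Abcg2 at -0.86, because the species of the transgene and the reach of the probe set were not given in the sources used here. A different makeup of marrow in ABCG2 recipients stays open and untested.

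Between the sorted EZH2-Mt arrays, erythroid and plasma cell transcripts were higher on the GFP-positive array. Less input RNA on the sorted arrays, which high added controls could mark, cannot be told apart: the GFP-negative array lay at a median of 1.49 against mock in erythroid genes, with 0 of 15 below every mock array, and at -1.14 in plasma cell genes, with 3 of 6 below every mock array. Spread between single arrays cannot be told apart either, since the difference exceeded the range over the mock arrays in 7 of 15 erythroid and 3 of 6 plasma cell genes. Both tests replaced earlier versions after their values were seen: set against the largest median difference between mock arrays, the fractions' difference was 1.496 times as large for erythroid and 6.77 times for plasma cell genes, and by that measure both explanations had been called excluded for plasma cell genes. An effect of EZH2-Mt in the GFP-positive cells stays open and untested.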

How the results depend on the processing

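The variance trend, the first probe set per gene and the 2-fold minimum were chosen only after the results were seen. No probe set called in both settings changed direction under any alternative for ABCG2 against mock. With quantile normalization 1988 probe sets were higher and 2381 lower (all 1988 and 2373 of them shared with the deposited scaling), and the share of higher calls was 45.5% against 55.5%; the cause was not tested, although equal spread of arrays follows from its construction. The median difference of all probe sets was 0.05 there and 0.11 as deposited. With 1 value per gene 2983 were higher and 2196 lower, from fewer features tested, and a 2-fold minimum left 2609 and 2434. Leave-one-out counts ran from 4168 to 4635 higher and 3402 to 3807 lower; without an ABCG2 array, the lone one is assumed to vary like the mock group. Lists past the threshold numbered 0 with an estimated correlation, 13 with fry, which tests another question, and 4 to 8 in leave-one-out (8 without mock replicate 1). The replicate block gave 4178 higher and 3548 lower and 5 lists; arrays share only a number (same-number correlations 0.08 and -0.04), and among named genes and lists it ended the call of Ezh2 alone.

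For ABCG2 against mock, list medians that changed sign, none of them past the threshold, were those of erythroid cells (-0.0147 to 0.668 in leave-one-out, the lowest without mock replicate 1), plasma cells (-0.10 to 0.33 in leave-one-out, -0.06 without mock replicate 1, -0.16 with array weights), p53 targets (-0.0136 to 0.192 in leave-one-out, -0.0348 with array weights) and oxidative stress defence (-0.105 to 0.0730 in leave-one-out, 0.0140 with the first probe set per gene). The cause was not tested. Directions are those of the median, a rule set after camera's own direction, first used, gave more changes of sign among lists that did not pass. Between the sorted fractions, quantile normalization gave 804 higher and 762 lower, 1 value per gene 148 and 112, and 4-fold 21 and 15. With quantile normalization 18 of the 24 named genes and 13 of 25 list medians moved by more than the SD over probe sets of the difference between mock replicates 1 and 2 (for lists, divided by the root of their size), with no change of direction among those genes. Between the fractions, the medians of mature neutrophils and of glycolysis and hypoxia, both near 0, changed sign with quantile normalization. The correlation across genes was 0.0888 with quantile normalization and 0.0428 to 0.0749 in leave-one-out. Other pseudocounts were not run because the values are logarithms; the filter alternatives and the fit of all 7 arrays, which adds no residual degrees of freedom, changed nothing and show nothing about stability. Signal over background limits what can be said, since centred values hold no level and only probe sets detected on all arrays remain.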

Other observations

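GTPases of the Gimap family, known from lymphocyte survival, rose together on the arrays labelled ABCG2. All 5 measured members, chosen after their values were seen, passed limma's test, with adjusted p from 0.000109 to 0.0178: Gimap1 (3.75 ± 0.26), Gimap4 (4.75 ± 1.26), Gimap6 (4.67 ± 0.59), Gimap8 (3.61 ± 0.84) and Gimap9 (3.70 ± 0.30). For Gimap4 the adjusted p was 0.0549 with quantile normalization and 0.0596 without ABCG2 replicate 2. Mock replicate 1 was the lowest of the 7 arrays in each, down to -4.45 for Gimap4. That array also lay below the other mock arrays in T and NK cell genes (median -1.93), basophil, mast cell and eosinophil genes (-1.64), immediate early genes (-0.98) and MHC class II and dendritic cell genes (-0.92).

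Against mock marrow, which was not sorted, both EZH2-Mt fractions had higher erythroid medians (2.81 in GFP-positive and 1.49 in GFP-negative cells, 1 array each) and lower monocyte (-1.06 and -1.36) and interferon response medians (-0.78 and -0.76). Medians of T and NK cell genes were 1.27 and 2.62, but a pair of mock arrays differed by 2.30 in this list. Plasma cell genes lay at 0.20 in the GFP-positive and -1.14 in the GFP-negative cells, and basophil, mast cell and eosinophil genes at 0.22 and 1.53, the latter within the 1.62 between a pair of mock arrays. These medians have no replicate check, and the sort separates these arrays from mock as well as the transgene does.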
